A study of Mus musculus with 4 samples.

How the data were processed

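CD45+ immune cells isolated from the small intestine of male mice aged 2 to 3 months were profiled with droplet-based single-cell RNA sequencing (10x Genomics Chromium, end-counting chemistry). The 4 libraries formed 4 groups with 1 library per group, and each library pooled cells of 2 mice. According to the labels, about 10000 live cells with a viability above 70% were loaded per library, with reagents planned for the capture of 6000 cells. The sample labels name version 3 of the reagent kit and the series design names version 3.1, so the exact version is left open. The submitters' processing notes name Cell Ranger 6.0.1, the genome build mm10, R 4.0.2 and Seurat 4.0.0. The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, as the authors obtained them from Cell Ranger after its call of cell-containing barcodes. The values were checked to be whole numbers with library totals that differ, so no normalization had been applied. R and Seurat are named without a role, and none of their output was used here.

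Counts were processed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scanpy 1.11.5, scikit-learn 1.9.0 and igraph 0.11.9, and figures were drawn with matplotlib 3.10.9. Gene positions were taken by Ensembl ID from GENCODE M21 (GRCm38/mm10), in which 32235 of the 32285 IDs of the matrices were found. Barcodes with at least 200 detected genes and at most 15% mitochondrial UMIs were kept. Doublet scores were computed per library with Scrublet. Its automatic threshold marked 1.45%, 1.74%, 0.170% and 0.335% of barcodes in the B6 control, B6 MR, Apc control-feces and Apc MR-feces libraries. These shares lay below the loading-based expectation of 4.81%, 4.51%, 4.71% and 3.34%, so the threshold did not separate doublets in these libraries. The barcodes with the highest scores were therefore removed up to an expected 0.8% per 1000 barcodes, which took out 289, 254, 278 and 140 barcodes. Some of these had also failed the filter, and 4750, 4928, 5305 and 3962 cells were kept.

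The 4 libraries were clustered together. Counts were scaled to 10000 per cell and log-transformed, genes seen in fewer than 10 cells were left out, and the 2000 most variable genes were used without immunoglobulin genes, T cell receptor variable segments, ribosomal protein genes and mitochondrial genes. Values were scaled with a maximum of 10, reduced to 30 principal components and joined to 15 neighbours per cell, and Leiden clusters were found at resolution 1.0 with seed 0. Clusters were named from 28 marker lists fixed before the data were examined, 6 of them for cells that are not immune. A marker counted for a cluster when it was detected in more than 10% of its cells and lay more than 0.5 log2 units above the other cells of the same libraries, in CPM (UMIs scaled to a common total), with 20 CPM added to both. A name needed at least 3 markers, at least a fraction of 0.4 of its list and a margin of 0.1 over the next class, and no other class could have more of its own markers among the 10 genes with the highest fold and at least 50 CPM. A cluster whose cells had a median below 1/3 of their library's median UMIs needed an own marker there as well. Alternative clusterings were named without the condition on markers of other classes among these 10 genes. Cluster 7 reached 0.400 of the neutrophil list, with G0s2 and Retnlg of that list among its 10 genes, but 0.385 of a B cell list, and stayed unnamed for want of the margin. These naming thresholds were set after the data had been seen, and the names are given as "-like" classes. Clusters of CD8 T cells, gamma-delta T cells and NK cells expressed overlapping markers and were joined to 1 class, and clusters named by the CD4, regulatory or naive T cell lists made up the CD4 T-like class. T and NK-like cells are this class together with the CD4 T-like class.

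With 1 library per group, no test was run, no p-value was computed and no genes were counted as changed. Shares of named immune cells are given with odds ratios and exact conditional 95% intervals, and shares within 1 library with exact Clopper-Pearson 95% intervals. Levels were computed from UMIs summed per library and class, as CPM of the class total, in classes with at least 100 kept cells in both libraries. The log2 ratio of MR over control used a prior count of 0.5 and an exact conditional binomial 95% interval. For 24 gene lists fixed beforehand, the median log2 ratio of the members with at least 20 UMIs over both libraries was taken. Its interval came from 1000 Poisson draws of the counts. Its percentile was read among 10000 random lists of the same size, matched on mean expression in 20 bins. All intervals, percentiles and floors cover counting error in these libraries only and say nothing about the spread between mice. A share or level with a count of 0 was set against a floor of 3 counts over the class in that library. In 1 of 96 described lists, members at 0 moved the median when set to that floor.

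The named genes follow a rule fixed before the data were examined. It takes, in each of the 4 classes with the most cells in their smallest library, the 3 genes with the highest and the 3 with the lowest log2 ratio among genes with at least 50 CPM in 1 library and at least 30 UMIs over both. Immunoglobulin genes, T cell receptor segments, ribosomal protein and mitochondrial genes, Xist, Y-linked genes, markers of cells that are not immune and genes below a fraction of 0.1 of their highest class in both libraries were left out there. It also takes up to 4 members of each described list, those with the largest absolute log2 ratio at 50 CPM or more, and the markers Cd4, Cd8a, Cd8b1, Trdc, Foxp3, Ifng, Gzmb and Pdcd1 with Mat2a, Cth, Cbs and Asns. Trac is not named by the rule and was added to the markers. The symbols Il26, Mx1, Mars1, Trgc1, Trgc2 and Trgv7 of the lists matched no symbol in the matrices.

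Free RNA was estimated from the share of UMIs that immunoglobulin A heavy chain and enterocyte genes took in T and NK-like cells, relative to their share in all kept cells. It came to 3.31%, 3.09%, 4.05% and 1.75% of the UMIs of T and NK-like cells in the same order of libraries, with these genes at 2.33%, 2.51%, 0.999% and 7.32% of UMIs in all kept cells. Beside shares of cells with a UMI of a gene, the share in B-like cells is given as background. Such shares were also computed after each cell was thinned to 1500 UMIs, leaving out cells with fewer.

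The steps were tested on simulated data: counts were drawn from the average rates of the 2 libraries of a pair at their own depths, with known folds put into 200 genes, or 66 to 67 per fold, drawn in each class from the 2665 to 3491 genes with at least 50 CPM and 30 UMIs, and a fold counted as recovered when its interval left out 0 on the right side. In the B6 pair, all genes with a 2-fold or 4-fold difference were recovered in the 3 largest classes, as were all with a 1.5-fold difference in B-like and CD8, gamma-delta T or NK-like cells and 98.5% in CD4 T-like cells. In the Apc pair, recovery at 1.5-fold was 100% in CD8, gamma-delta T or NK-like cells, 86.6% in B-like cells and 65.7% in CD4 T-like cells. At 2-fold it was 100%, 100% and 89.6%, and at 4-fold 100% in all 3. These rates do not cover genes with lower counts, among them list members with 20 to 29 UMIs. Intervals of genes with no difference held 0 for 95.1% to 96.1% of genes. Of lists shifted by 0.5 log2 units, 23 of 23, 24 of 24 and 23 of 23 lay above percentile 97.5 in CD8, gamma-delta T or NK-like, CD4 T-like and B-like cells of the B6 pair, and 23 of 23, 23 of 24 and 22 of 23 in the Apc pair. Lists with no shift fell outside percentiles 2.5 to 97.5 in at most 2 cases per class. The simulated libraries differed only by counting error and the set folds. In the real Apc pair, log2 ratios had standard deviations of 0.67 in B-like, 0.91 in CD4 T-like and 0.59 in CD8, gamma-delta T or NK-like cells. The simulated rates for lists do not cover differences that wide. Share intervals held the true value in 95.7% and 95.0% of 300 simulations.

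B6 libraries were compared with each other and Apc libraries with each other. The 2 comparisons share no library and were never pooled, since strain background, antibiotics, transplant, diet and tumors differ between them. The alternatives tried were a stricter cell filter of 500 genes and 10% mitochondrial UMIs, no cell filter, no doublet removal, resolutions 0.5 and 2.0, seed 1, 2 other denominators, thinning to 1500 UMIs with new clusters, median-of-ratios scaling, CPM without ribosomal, mitochondrial and immunoglobulin genes, a prior count of 2, list members with at least 1 or at least 100 UMIs, the mean of each cell's CPM, clusters weighted alike, subtraction of free RNA and, chosen after seeing the data, T and NK-like cells as 1 class. The weighting of clusters used only clusters with at least 10 cells in both libraries of a pair. Levels of plasma-like and macrophage-like cells in the Apc pair were left out, since 1 library held 93 and 76 of these cells. Results for 2 single genes are not reported here.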

Results

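Immune cells expressing CD45 from the small intestine of male mice were sequenced as 4 single-cell libraries, each from 2 pooled mice. One pair of libraries came from tumor-free C57BL/6J mice (B6) fed for 3 to 4 weeks with a control diet holding 0.86% methionine or a methionine-restricted (MR) diet holding 0.172%. The other pair came from Apc-min mice (Apc), which carry a mutant copy of the tumor suppressor Apc and had intestinal tumors. These mice had drunk ampicillin at 1 g/L with enrofloxacin at 0.575 g/L for 1 week, had then received 100 µl of fecal suspension by gavage on each of 7 days, from B6 donors on the control diet or on the MR diet, and were sampled 3 to 4 weeks after the transplant while eating chow. The libraries are called B6 control, B6 MR, Apc control-feces and Apc MR-feces.

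The libraries held 6011, 5634, 5892 and 4176 cell barcodes in that order, with 25914574, 26080998, 22536361 and 7537407 UMIs in total. A median barcode had 3202, 3388, 3172 and 1222.5 UMIs and 1419, 1433, 1529.5 and 615 detected genes. The Apc MR-feces library was thus the shallowest per cell. After filtering and doublet removal, 4750, 4928, 5305 and 3962 cells were kept. Each group had 1 library, so no replicate check exists for any difference, and the 95% intervals given with values cover counting error only.

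The kept cells fell into 23 clusters, numbered from 0 to 22, of which 21 were named as 11 classes of immune cells. Another was epithelial-like, and cluster 7 stayed unnamed. Named immune cells numbered 4585, 4811, 5183 and 3947 in the 4 libraries. Most cells were B-like, CD4 T-like, or in the class that joins CD8 T, gamma-delta T and NK-like cells, which share cytotoxic genes in the intestinal epithelium. The Apc MR-feces library filled clusters of its own: it gave 1160 of its cells to cluster 3, 726 to cluster 4 and 925 to cluster 17, whereas the B6 control, B6 MR and Apc control-feces libraries gave 51, 69 and 64 cells to cluster 3, 0, 1 and 2 to cluster 4, and 29, 63 and 21 to cluster 17. The Apc control-feces library in turn gave 1086 cells to cluster 6, to which the Apc MR-feces library gave 2. In the B6 control, B6 MR and Apc control-feces libraries, cluster 17 had medians of 1287, 1560 and 1113 UMIs, against 3214, 3265 and 2589 in the B-like cluster 0. Cluster 3 had 1143, 963 and 1809 there, against 3050.5, 3190 and 2175 in cluster 2 of the same class. In clusters 3 and 17, low depth and a state of the cells cannot be told apart.

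**Figure D1:**
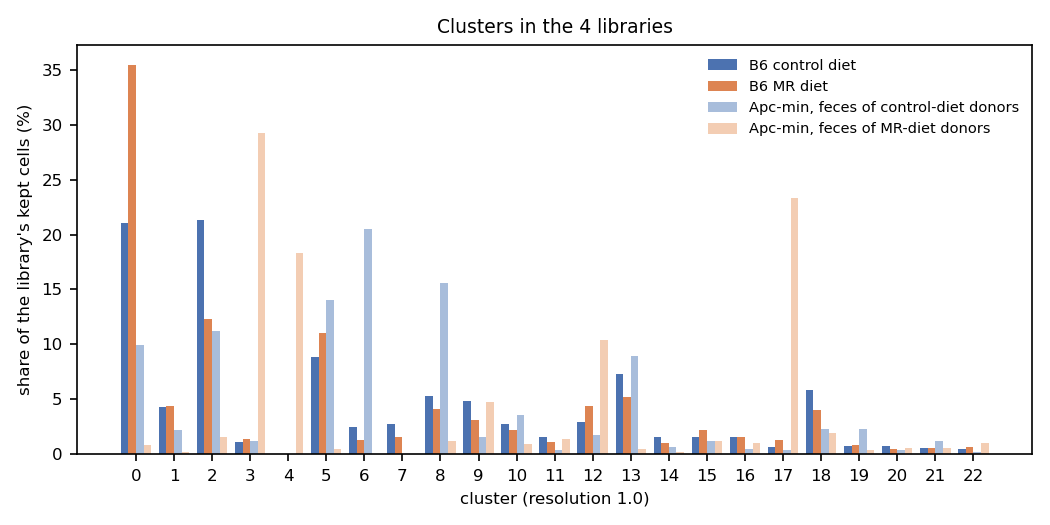
Share of each library's kept cells (%, vertical axis) in each cluster at resolution 1.0 (horizontal axis), with 1 bar per library of 2 pooled mice. The Apc MR-feces library has 1160 cells in cluster 3 and 925 in cluster 17, and the Apc control-feces library has 1086 in cluster 6.

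The B6 comparison asks what the diet itself does to the immune cells of a tumor-free intestine. B-like cells made up 42.1% of named immune cells in the MR library and 26.8% in the control library, and antibody-secreting plasma-like cells 4.45% and 3.05%. The CD8, gamma-delta T or NK-like class was lower, at 34.2% against 45.3%, as were CD4 T-like cells, at 8.46% against 12.1%. Over T and NK-like cells, transcripts of Foxp3, the lineage-defining factor of regulatory T cells, lay at 10.4 CPM in the MR library against 29.4 CPM. In CD4 T-like cells, genes of T cell activation, NF-kappaB signalling and the type 2 and type 17 cytokine programs lay lower. The type 17 list did not do so with the stricter cell filter. Genes of the type I interferon response lay higher in the MR library in CD8, gamma-delta T or NK-like cells and in B-like cells, but lower in macrophage-like cells.

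The odds of a named immune cell being B-like were 1.98 times those in the control library (interval 1.82 to 2.16), and 1.48 times for plasma-like cells (1.18 to 1.85), or 1.24 times (0.974 to 1.59) with the stricter cell filter. They were 0.625 times for the CD8, gamma-delta T or NK-like class (0.575 to 0.680), 0.673 times for CD4 T-like cells (0.586 to 0.771) and 0.663 times for macrophage-like cells (0.547 to 0.803), which stood at 4.07% against 6.02%. ILC2-like cells, innate lymphoid cells that make type 2 cytokines, stood at 1.10% against 1.61%, with an odds ratio of 0.679 (0.467 to 0.982). These shares sum to a whole: among immune cells other than B and plasma cells, the log2 odds were 0.04 for the CD8, gamma-delta T or NK-like class, −0.11 for CD4 T-like cells, −0.15 for macrophage-like cells and −0.13 for ILC2-like cells, each with an interval that includes 0.

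**Figure D2:**
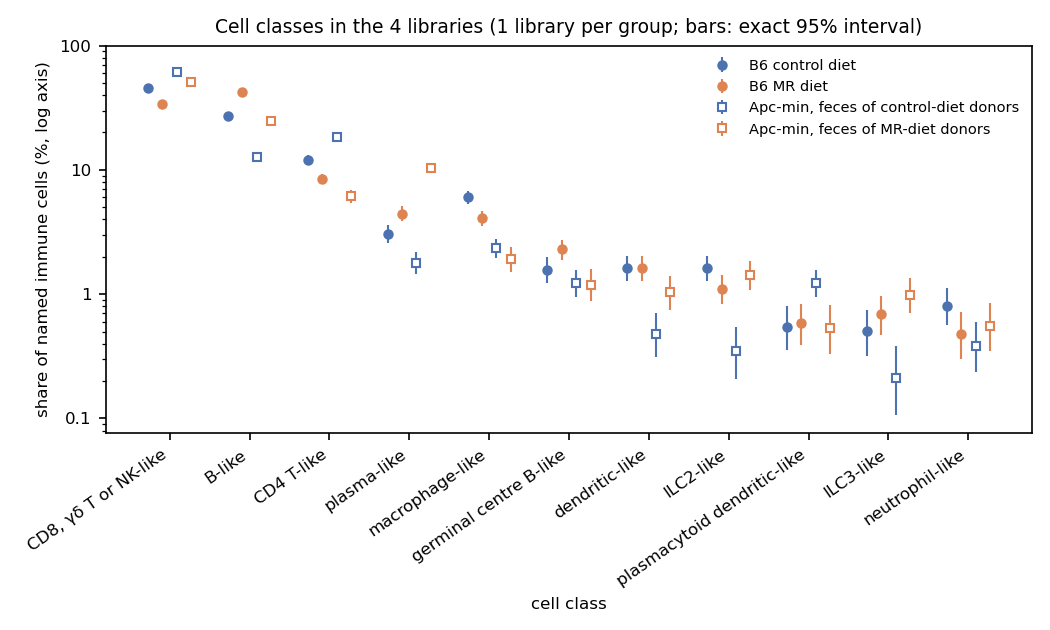
Share of named immune cells (%, log axis) in each of 11 cell classes (horizontal axis), with filled circles for the B6 libraries and open squares for the Apc libraries, and bars for the exact 95% interval of 1 library. B-like cells lie at 42.1% in the B6 MR library against 26.8%, and at 24.5% in the Apc MR-feces library against 12.8%.

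In CD4 T-like cells the median of all measured genes was −0.04 on the log2 scale, so ratios are given as they are. The class also differed in its make-up: in its cluster 9, 21.9% of cells had a Foxp3 UMI in the MR library and 40.4% in the control library. The type 2 list, with 6 measured members, had a median of −1.12 (−1.54 to −0.90) at percentile 0.00 of matched random lists, and 5 members had intervals below 0 and 0 above. Among them were Areg, an epidermal growth factor family ligand involved in tissue repair, at −1.37, and the transcription factor Gata3 at −0.77. The type 17 list had a median of −0.37 (−0.58 to −0.19) at percentile 0.48, with 4 of 11 members below 0 and 0 above. It included the cytokine Il17a, at 192 against 525 CPM, a ratio of −1.45 (−1.63 to −1.27). With the stricter cell filter the median of this list, relative to all genes, was 0.03 in place of −0.33. The T cell activation and costimulation list had a median of −0.30 (−0.46 to −0.24) at percentile 0.00, with 14 of 21 members below 0 and 1 above. Its antigen-receptor response genes Nr4a1 and Nr4a3 lay at −0.98 and −0.93, the costimulatory receptor Tnfrsf9 at −0.84 and the interleukin-2 receptor chain Il2ra at −0.82. The NF-kappaB and inflammatory cytokine list had a median of −0.41 (−0.57 to −0.25) at percentile 0.00, with 10 of 19 members below 0 and 1 above, among them the inhibitor Nfkbia at −1.22 and Cd83 at −1.01. Immediate early and heat shock genes, which respond to tissue dissociation, had a median of −0.14 (−0.24 to −0.06) at percentile 0.42 beside them, or 0.02 relative to all genes after thinning, and ribosomal protein genes took 24.6% against 21.8% of UMIs.

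Other lists in the same CD4 T-like cells had medians on both sides of 0. Inhibitory receptors had a median of −0.30 (−0.39 to −0.09), with Ctla4 at −0.52 and Lag3 at −0.47 but Btla at 0.50. Tissue residency and gut homing genes had a median of −0.26 (−0.36 to −0.15), with the chemokine receptor Ccr2 at −1.11 and the aryl hydrocarbon receptor Ahr at −0.75. The interferon-gamma response and class I presentation list stood at −0.14, with the GTPase Iigp1 at −1.18, and the type I interferon list at −0.07 (−0.21 to 0.03). Naive and central memory genes had a median of −0.06. Cytotoxic effector genes had a median of 0.04 with members on both sides, among them Gzma at 1.02 and Ccl5 at 0.81, and Gzmb at −0.55. With the stricter cell filter Ccl5 lay at −0.28. Methionine cycle, salvage and polyamine genes had a median of 0.12 (−0.07 to 0.24), while Odc1, the rate-limiting enzyme of polyamine synthesis, lay at −0.81 and Mat2a, which makes S-adenosylmethionine, at 0.20 with an interval that includes 0. Among the genes ranked, the lowest ratios were those of the enkephalin precursor Penk at −2.42 (−3.21 to −1.75), Neb at −2.24 and the phosphatase Dusp4 at −1.71. The highest were those of Bloc1s1 at 0.97, the heat shock gene Hspa1a at 0.81 and Ccl5. The B6 control and MR libraries differed little in depth here, with medians of 3826 and 3762 UMIs per CD4 T-like cell. They differed in quality before filtering. Of 6011 control barcodes, 1022 exceeded the mitochondrial limit of the filter and 412 had too few genes for it. In the MR library these were 478 and 109 of 5634. Median mitochondrial shares per barcode were 6.6% and 5.6%. In kept CD4 T-like cells, mitochondrially encoded transcripts took 6.26% and 6.00% of UMIs. An effect of this quality difference on the ratios is not excluded.

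Over all T and NK-like cells, Foxp3 had 83 UMIs in the B6 MR library and 305 in the control library, a ratio relative to all genes of −1.47 (−1.84 to −1.12), and in the CD4 T-like class, which Foxp3 helps to name, it lay at 50.5 against 130 CPM. A Foxp3 UMI was found in 1.85% and 3.76% of T and NK-like cells at median depths of 3734 and 3681 UMIs, and in 0.905% and 2.71% after thinning to 1500 UMIs, which left out 171 and 195 cells. In B-like cells, the background, it was found in 0 of 2026 and 0 of 1231 cells at median depths of 3297.5 and 3318 UMIs. Cd8b1, a chain of the CD8 coreceptor of conventional CD8 T cells, lay at 52.9 against 32.0 CPM, a ratio of 0.72 (0.51 to 0.94), and was seen in 6.63% against 4.82% of cells, or in 4.42% against 3.40% after thinning, where the interval of the log2 odds included 0, with 0.0494% and 0.244% in B-like cells. The other markers had small ratios: Cd4 −0.25, Cd8a −0.10, Trac 0.11, Trdc 0.04, Gzmb 0.11, Ifng −0.22 (−0.47 to 0.03) and Pdcd1 0.15 (−0.26 to 0.56). Mat2a lay at 0.05 (−0.07 to 0.17). The transsulfuration enzymes Cth and Cbs had 1 and 0 UMIs in the MR library and 0 in the control library, and asparagine synthetase Asns had 17 and 16, so differences in these genes were not detectable at this depth.

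In CD8, gamma-delta T or NK-like cells of the B6 pair, the type I interferon response list had a median of 0.28 (0.15 to 0.34) at percentile 100, with 10 of 29 members above 0 and 0 below. Its ubiquitin-like effector Isg15 lay at 0.44 and the DNA-sensing family genes Ifi206 and Ifi209 at 0.43 and 0.33. Genes of nuclear-encoded oxidative phosphorylation had a median of 0.22 (0.17 to 0.23), with 34 of 41 above 0, and glycolysis genes one of 0.11. Ribosomal protein genes stood beside them at 0.22, with 16.7% of the class's UMIs in the MR library and 14.4% in the control library, and mitochondrially encoded transcripts at −0.08, with 5.09% and 5.61%. Inhibitory receptors had a median of −0.15 (−0.19 to −0.04) at percentile 0.80, with Lag3 at −0.41, Cd101 at −0.38 and the exhaustion-linked factor Tox at −0.30. Cytotoxic effector genes had a median of 0.01 (−0.03 to 0.08), with 10 of 23 members above 0 and 5 below, among them Gzmk at 0.48, Ccl4 at 0.33 and Ccl5 at 0.27. The class also differed in its make-up. Cluster 2, with Lag3 among its top genes, held 606 cells in the MR library and 1012 in the control library. Cluster 5, with Gzmk, Ccl4 and Ccl5 among its top genes, held 542 and 421.

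Pathways that use methionine or respond to its lack stood close to all genes in this class. The methionine cycle list had a median of 0.04 (−0.05 to 0.14), with Mat2b at 0.29 and the salvage enzyme Mri1 at −0.28. Serine, folate and one-carbon genes stood at −0.04, transsulfuration, glutathione and sulfide oxidation genes at 0.05, and targets of the amino acid stress factor ATF4 at 0.06 (−0.07 to 0.12). Amino acid transporters had a median of −0.11 (−0.21 to −0.05), with the cationic transporter Slc7a1 at −0.43 and Slc3a2 at −0.30. Activation genes stood at −0.02, interferon-gamma response genes at 0.01, cell cycle genes at −0.07, NF-kappaB genes at −0.10 and p53 and apoptosis genes at 0.07, although the proapoptotic Bcl2l11 lay at −0.59. The highest ratios were those of the NK receptor Klra7 at 0.83, the transcription factor Zeb2 at 0.74 and Erh at 0.65. The lowest were Gm156 at −1.11, Lars2 at −0.81, and Gm42418, a locus that overlaps a ribosomal RNA repeat, at −0.92.

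In B-like cells of the B6 pair, the type I interferon response list had a median of 0.19 (0.10 to 0.32) at percentile 99.96, with 6 of 27 members above 0 and 0 below. Ifi27l2a lay at 0.63 and Ifi203 at 0.37. Transsulfuration and glutathione genes had a median of 0.13, with the peroxidase Gpx1 at 0.32, and oxidative phosphorylation genes one of 0.18 with 27 of 41 above 0. Ribosomal protein genes stood at 0.16, with 28.0% against 25.1% of UMIs, and mitochondrially encoded transcripts at −0.20, with 6.34% against 7.33%. Class II presentation genes had a median of −0.12, with 9 of 14 below 0 and the costimulatory ligand Cd86 at −0.58. Amino acid transporters had a median of −0.28 (−0.35 to −0.14), with 7 of 14 below 0 and 0 above. Immediate early and heat shock genes had a median of −0.21, with Fosb at −0.95, and NF-kappaB genes one of −0.15. The methionine cycle list stood at 0.04, and cytotoxic effector genes, which are typical of T and NK cells, at −0.30 (−0.66 to −0.18). With free RNA subtracted the cytotoxic list stood at 0.03 relative to all genes. The highest ratios were those of Tsc22d3, a glucocorticoid-induced gene, at 0.81, Zfp36l2 at 0.75 and Dynll1 at 0.74, and the lowest those of Nr4a3 at −1.45, Gm6377 at −1.13 and Gm42418 at −0.99.

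In plasma-like cells of the B6 pair the median of all genes was −0.13, and ratios are given relative to it. The endoplasmic reticulum chaperone Fkbp11 lay at 1.27 (1.04 to 1.52), Hspa1b and Hspa1a both at 1.36, and plasma cell secretion genes had a median of 0.29, with 14 of 18 members above all genes and 1 below, among the former Creld2 at 0.61 and Mzb1 at 0.59. Class II presentation genes had a median of −0.99 and NF-kappaB genes one of −0.70, with H2-Aa at −1.63 and Il1b, a myeloid cytokine, at −3.25. Lists typical of other cells lay lower too, naive and central memory genes at −0.74, tissue residency genes at −0.48 and T cell activation genes at −0.40. Immediate early and heat shock genes stood at −0.30, with Egr1 at −1.68 but the heat shock members Hspa1a and Hspa1b above. Cell cycle genes stood at 0.38, oxidative phosphorylation genes at 0.30 and type I interferon genes at 0.09. Lbh lay at −1.38. The pancreatic lipase gene Pnlip lay at −1.55, but on the other side of 0 with the stricter cell filter or without doublet removal. In macrophage-like cells, type I interferon genes had a median of −0.43 (−0.55 to −0.20) at percentile 0.00, with the antiviral gene Rsad2 at −1.83 (−2.71 to −1.09), and NF-kappaB genes one of −0.33, with the chemokines Ccl3 at −1.10, Ccl4 at −1.06 and Cxcl2 at −0.74. Class II genes stood at 0.06, with Cd74 at 0.29, but at −0.09 without doublet removal, oxidative phosphorylation genes at −0.01 and ribosomal protein genes at −0.02.

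The Apc comparison asks whether feces of MR-diet donors carry an effect on intestinal immune cells of tumor-bearing recipients that ate the same chow. Plasma-like cells made up 10.4% of named immune cells with feces of MR-diet donors against 1.79% with feces of control-diet donors, and B-like cells 24.5% against 12.8%. CD4 T-like cells made up 6.13% against 18.2%, and the CD8, gamma-delta T or NK-like class 51.3% against 61.0%. In the control-feces library, however, more cells of the CD4 T-like class had a Cd8b1 UMI (45.6%) than a Cd4 UMI (26.3%). The directions for B-like cells and for both T cell classes each turned under some of the settings given below. Over T and NK-like cells, Ifng, the cytokine of antitumor T cell responses, and Cd8b1 lay lower in the MR-feces library, at 15.8 against 54.8 CPM and 38.7 against 96.4 CPM, and Foxp3 was at 14.1 against 7.75 CPM. With clusters weighted alike, Ifng and Foxp3 lay on the other side of 0. Type I interferon response genes lay lower in B-like cells, at a median of −0.57 relative to all genes, or −0.24 with clusters weighted alike. The libraries also differed in quality: ribosomal protein genes took 38.4% against 24.8% of UMIs in B-like cells, 36.4% against 18.7% in CD4 T-like cells and 24.0% against 15.3% in the CD8, gamma-delta T or NK-like class, and mitochondrially encoded transcripts 3.54% against 5.98%, 2.83% against 4.71% and 2.67% against 4.46%.

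The odds ratio of the Apc pair was 6.36 (5.04 to 8.09) for plasma-like cells, 2.21 (1.98 to 2.47) for B-like cells, 0.293 (0.252 to 0.341) for CD4 T-like cells, 0.675 (0.620 to 0.735) for the CD8, gamma-delta T or NK-like class and 4.13 (2.39 to 7.48) for ILC2-like cells, at 1.42% against 0.347%. Macrophage-like cells stood at 1.93% against 2.33%, an odds ratio of 0.821 (0.606 to 1.11), which was 1.53 (1.16 to 2.01) with the stricter cell filter and 0.452 (0.298 to 0.672) without a filter. Different clusters held the classes: of the CD4 T-like cells, 829 of 944 were in cluster 8 in the control-feces library and 188 of 242 in cluster 9 in the MR-feces library, and B-like cells were mostly in cluster 0 and cluster 17. In the control-feces library, 69.0% of cluster 8 cells had a Cd8a UMI, 49.2% a Cd8b1 UMI and 23.6% a Cd4 UMI. The CD4 T-like class there thus held more cells with a CD8 marker than with Cd4. A Cd8a UMI was found in 63.2% of the class in the control-feces library and 6.20% in the MR-feces library. The log2 odds of CD4 T-like cells were 0.22 at resolution 2.0 and 0.28 with the stricter cell filter, in place of −1.77. Those of B-like cells were −0.14 after thinning to 1500 UMIs, where plasma-like cells made up 31.4% of the MR-feces cells left, and 0.17 with the stricter filter, in place of 1.14. Those of the CD8, gamma-delta T or NK-like class were 0.63 among immune cells other than B and plasma cells, in place of −0.57.

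Ribosomal protein genes took more of the UMIs in the Apc MR-feces library, and the median log2 ratio of all genes was −0.52 in B-like, −0.61 in CD4 T-like and −0.36 in CD8, gamma-delta T or NK-like cells. In CPM without ribosomal, mitochondrial and immunoglobulin genes it was −0.27, −0.29 and −0.23. Ratios of lists and genes within these classes are therefore given relative to the median of all genes in CPM. In CD4 T-like cells, clusters 8 and 9 stood against each other, and cluster 8 of the control-feces library held more cells with Cd8a than with Cd4. Cytotoxic effector genes had a relative median of −1.46 in the class. Counts of members in the Apc pair are those whose intervals lay above or below the median of all genes, here 14 of 21 below and 1 above. The granzyme Gzma lay at −2.74, Gzmb at −2.41 and Ccl5 at −2.30. Tissue residency genes had a median of −1.10, with the integrins Itga1, which binds collagen, at −3.77 and Itgae, which binds epithelial E-cadherin, at −2.38. Naive and central memory genes had a median of 1.98, with the lymph node homing receptor Ccr7 at 3.57 and Klf2 at 2.66. The type 2 list, with 4 measured members, stood at 2.39, with Il1rl1, the interleukin-33 receptor, at 4.64 (4.04 to 5.34), Areg at 2.96 and Gata3 at 1.82. The type 17 list stood at 1.25, with Il22 at 3.44 and Il17a at 2.12, and the NF-kappaB list at 1.18, with Cxcl2 at 6.58 but Ccl4 at −2.12.

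The activation and costimulation list had a relative median of 1.23 in CD4 T-like cells of the Apc pair, with 14 of 21 members above all genes and 4 below. The costimulatory receptors Tnfrsf4 and Tnfrsf9 lay at 3.81 and 3.21, whereas Cd38 and Nr4a2 lay at −2.72 and −2.12. This median was 0.59 with the stricter cell filter, 0.58 with clusters weighted alike and, with T and NK-like cells as 1 class, a setting chosen after seeing the data, 0.17. Type I interferon genes stood at −0.56, and in CPM at −1.18, or −0.91 with 3 members that had no UMI in 1 library set to their bound. Ribosomal protein genes stood at 1.51 and mitochondrially encoded transcripts at −0.08. The highest ratios were those of Tff1, from 25 UMIs, at 5.60, Ramp3, a receptor-modifying protein, at 5.30, and Il1rl1. The actin-severing gene Scin and the ceramide synthase gene Cers6 had 0 UMIs in the MR-feces library against 206 and 178, so they were at least 6.87-fold and 5.94-fold lower in CPM, against a floor of 3 counts over the class. Cd244a, an inhibitory receptor, had 2 against 611 UMIs, a relative ratio of −4.26 (−7.37 to −2.46). Median depth was 1219.5 against 3179.5 UMIs per CD4 T-like cell, and simulated 1.5-fold differences were recovered for 44 of 67 genes, which were drawn from the 3031 better measured ones.

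Over all T and NK-like cells of the Apc pair, ratios in CPM and relative to all genes were −1.79 (−2.26 to −1.36) and −1.42 for Ifng, −1.31 (−1.61 to −1.03) and −0.94 for Cd8b1, and 0.86 (0.30 to 1.39) and 1.23 for Foxp3. An Ifng UMI was found in 1.54% of cells with MR-diet feces and 10.6% with control-diet feces, at median depths of 1180 and 3295 UMIs, and in 1.74% and 6.05% after thinning to 1500 UMIs, which left out 1750 and 267 cells. A Cd8b1 UMI was found in 3.40% and 14.3% of cells, or 3.28% and 9.80% after thinning. For Foxp3 the shares were 1.41% and 0.999%, or 1.16% and 0.730% after thinning. The interval of the log2 odds for Foxp3 included 0 at both depths, so a difference in the share of cells was not detectable at this depth. In B-like cells, with median depths of 1014 and 2606 UMIs, the shares were 0.104% and 0.151% for Ifng, 0 and 0.452% for Cd8b1, and 0.104% and 0 for Foxp3. With clusters weighted alike in both libraries, the ratio in CPM was 0.10 for Ifng and −1.32 for Foxp3, each on the other side of 0. This setting leaves out clusters with fewer than 10 cells in either library. Among them are cluster 4, with 726 MR-feces cells, and cluster 6, with 1086 control-feces cells. Of the clusters used, cluster 5 had 19 and cluster 13 had 20 MR-feces cells, so these ratios come from a different subset of cells.

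Other markers in T and NK-like cells of the Apc pair had ratios in CPM of −0.36 for Cd4, −0.51 for Cd8a, −0.58 for Trdc, 0.12 for Trac, 0.03 for Gzmb and 0.46 (−0.31 to 1.17) for Pdcd1. Relative to all genes these were 0.00, −0.14, −0.21, 0.49, 0.40 and 0.82, so Cd4 lay at the level of all genes. With clusters weighted alike, Cd4 and Trac lay at 0.27 and −0.05 in CPM. Mat2a lay at −0.95 (−1.14 to −0.75) in CPM and −0.58 relative to all genes. Asns had 1 against 29 UMIs, a ratio of −2.34 (−7.88 to 0.07). Cth had 0 against 2 and Cbs 0 against 4 UMIs, for which no fold is given.

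**Figure D3:**
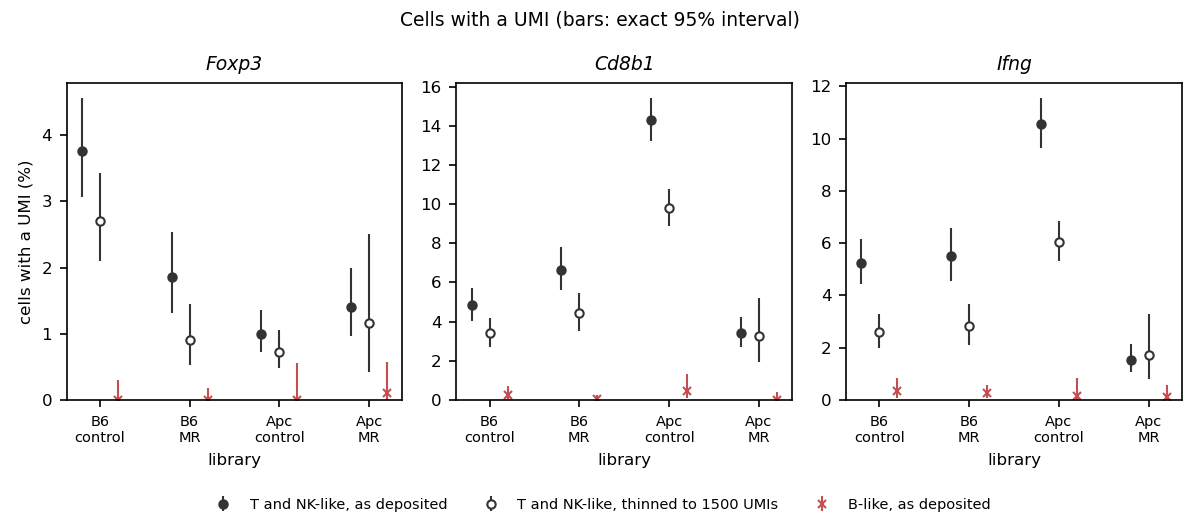
Share of cells with a UMI (%, vertical axis) of Foxp3, Cd8b1 and Ifng in each library (horizontal axis), for T and NK-like cells as deposited and thinned to 1500 UMIs and for B-like cells as background, with bars for the exact 95% interval. Ifng lies at 1.54% in the Apc MR-feces library against 10.6% in the Apc control-feces library, and Foxp3 at 1.85% in the B6 MR library against 3.76% in the B6 control library.

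In CD8, gamma-delta T or NK-like cells of the Apc pair, held mostly by clusters 3 and 4 in the MR-feces library, tissue residency genes had a relative median of −0.25, with 10 of 17 members below all genes and 3 above. The integrins Itga4 and Itga1 lay at −1.06 and −0.83 and the gut homing receptor Ccr9 at −0.78. With clusters weighted alike this median was 0.01. Cytotoxic effector genes had a relative median of 0.32, with the granzyme inhibitors Serpinb6b and Serpinb9 at 1.58 and 1.33 and the chemokine Xcl1 at 1.28, but Gzmk at −0.58, and this median was 0.71 with clusters weighted alike. Amino acid transporters had a median of −0.47, with 5 of 12 members below all genes and 2 above, among the former the glutamine transporter Slc38a1 at −0.88. The methionine cycle list stood at 0.20, although Mat2a and Mat2b lay at −0.56 and −0.43. ATF4 targets stood at 0.40, with Cebpb at 1.43 and Slc3a2 at 1.13, and Asns had 0 against 15 UMIs, too few for a fold to be given. Serine and one-carbon genes stood at −0.06 and transsulfuration genes at 0.18, or −0.15 with clusters weighted alike. Glycolysis and oxidative phosphorylation genes had medians of 0.65 and 0.75, with Gapdh at 1.30 and Atp5g1 at 1.48, beside ribosomal protein genes at 0.99 and mitochondrially encoded transcripts at −0.35.

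Type I interferon genes stood at −0.24 in the same class, at percentile 6.55 of matched random lists, with 10 of 27 members below all genes and 4 above. Ifi203 lay at −0.85 and Isg15 at 1.09. Interferon-gamma response genes stood at 0.11, although Gbp4 lay at −0.89, inhibitory receptors at −0.04 with Cd244a at −0.89 and Ctla4 at −0.71, and activation genes at 0.25, with Nr4a3 at 2.85 and Cd69, a retention and activation marker, at −1.27. With the stricter cell filter the activation list stood at −0.13. NF-kappaB genes stood at 0.40, cell cycle genes at 0.34 and p53 and apoptosis genes at −0.01. The highest ratios were those of the histone genes Hist1h2bc at 4.06 and Hist1h4n at 3.81 and of Crem, a cAMP-responsive transcription factor, at 3.27 (3.14 to 3.41). The lowest were Gm26532 at −2.98, Gm43065 at −1.90 and the autophagy gene Vmp1 at −1.76.

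In B-like cells of the Apc pair, held by cluster 0 in the control-feces library and cluster 17 in the MR-feces library, the type I interferon list had a median of −1.09 (−1.39 to −0.95) in CPM and −0.57 relative to all genes, at percentile 0.21, with 11 of 19 members below all genes and 1 above. The RNA sensor gene Ddx58 lay at −1.32, Ifi206 at −0.80 and Ifi203 at −0.79. Naive genes stood at −0.54, with the egress receptor S1pr1 at −0.96, and interferon-gamma response genes at −0.16. Class II genes stood at 0.26, with H2-Eb1 at 1.33 and its transcriptional regulator Ciita at −0.53. Transsulfuration, glycolysis and oxidative phosphorylation genes stood at 0.84, 0.81 and 0.83, ribosomal protein genes at 1.13 and mitochondrially encoded transcripts at −0.19. Cytotoxic effector genes stood at 0.84. The heat shock genes Hspa1a and Hspa1b lay at 5.53 (4.80 to 6.53) and 4.08 and Nr4a3 at 4.36. The peptide transporter gene Slc15a2 had 0 against 96 UMIs, at least 19.1-fold lower in CPM against a floor of 3 counts, Gm26532 lay at −3.21 and Arrdc3 at −2.03.

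On the GRCm38/mm10 genome, Foxp3 (ENSMUSG00000039521) lies on chromosome X from 7573644 to 7595245, Cd8b1 (ENSMUSG00000053044) on chromosome 6 from 71322788 to 71337494 and Ifng (ENSMUSG00000055170) on chromosome 10 from 118441046 to 118445892. Il17a (ENSMUSG00000025929) lies on chromosome 1 from 20730905 to 20734496, Areg (ENSMUSG00000029378) on chromosome 5 from 91139599 to 91148432, Nr4a1 (ENSMUSG00000023034) on chromosome 15 from 101254269 to 101274795 and Il1rl1 (ENSMUSG00000026069) on chromosome 1 from 40429570 to 40465415. Ifi203 (ENSMUSG00000039997) lies on chromosome 1 from 173920407 to 173942672, Isg15 (ENSMUSG00000035692) on chromosome 4 from 156199424 to 156200818, Mat2a (ENSMUSG00000053907) on chromosome 6 from 72432799 to 72439558 and Hspa1a (ENSMUSG00000091971) on chromosome 17 from 34969190 to 34972156.

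Side by side, both comparisons had higher odds of B-like and plasma-like cells with MR and lower odds of both T cell classes at the settings used throughout. Among immune cells other than B and plasma cells both T cell classes of the B6 pair had intervals that include 0, and in the Apc pair the log2 odds of the CD8, gamma-delta T or NK-like class were above 0. The Apc values of CD4 T-like and B-like cells also turned, with the settings given above. Across genes, the log2 ratios of the pairs had a Pearson correlation of 0.21 and a Spearman correlation of 0.27 over 3793 genes in B-like cells, 0.01 and 0.08 over 4845 genes in CD4 T-like cells, and 0.15 and 0.16 over 8510 genes in CD8, gamma-delta T or NK-like cells. These are correlations across genes of 4 libraries, and genes are not independent replicates. Oxidative phosphorylation and ribosomal protein genes lay above all genes in B-like and CD8, gamma-delta T or NK-like cells of both pairs. The type 2, type 17, activation and NF-kappaB lists lay below all genes in CD4 T-like cells of the B6 pair and above them in the Apc pair, and the type I interferon list lay above all genes in B-like cells of the B6 pair and below them in the Apc pair. The B6 type 17 value turned with the stricter cell filter, and the Apc libraries held most of their CD4 T-like cells in different clusters. Differences between the pairs were not tested.

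**Figure D4:**
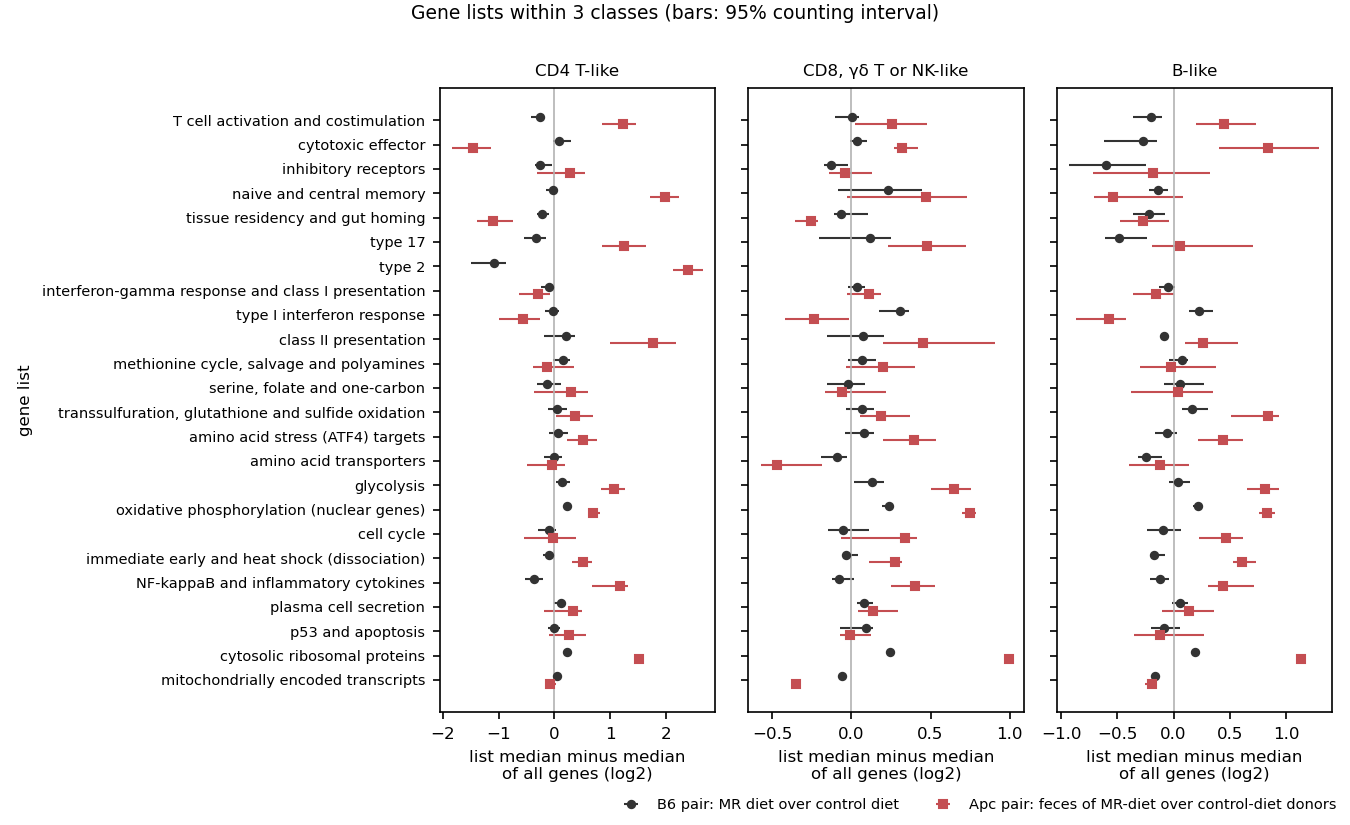
Median log2 ratio of 24 gene lists minus the median of all genes (horizontal axis, a separate scale for each panel), for MR over control, in 3 cell classes (panels), with circles for the B6 pair, squares for the Apc pair and bars for the 95% counting interval. In CD4 T-like cells the type 2 list lies at −1.08 in the B6 pair and 2.39 in the Apc pair.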

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

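The results below, except the share of B-like and plasma-like cells, lay on opposite sides of 0 in the B6 and Apc pairs, each with a counting interval that left out 0, and the difference between the pairs was not tested. Of the predictions for technical explanations in this part, only that for Foxp3 at 1500 UMIs per cell was written before its result was seen. Several other values come from alternatives chosen beforehand, but their use as tests was chosen afterwards.

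The log2 odds of ILC2-like cells were −0.56 in the B6 pair and 2.05 in the Apc pair, a difference of 2.60, but the B6 value was −0.13 (−0.68 to 0.40) among immune cells other than B and plasma cells. In CD4 T-like cells, lists relative to all genes differed by 1.54 for NF-kappaB and inflammatory cytokines (−0.37 and 1.18), 1.49 for T cell activation and costimulation (−0.26 and 1.23), 1.58 for type 17 (−0.33 and 1.25) and 3.47 for type 2 (−1.08 and 2.39). The Apc libraries held this class in different clusters, with Cd8a in 69.0% of the control-feces cells of cluster 8, the Apc activation value was 0.58 with clusters weighted alike and 0.17 with T and NK-like cells as 1 class, and the B6 type 17 value was 0.03 with the stricter cell filter. In B-like cells the cytotoxic effector list differed by 1.11 (−0.27 and 0.84), but with free RNA subtracted the B6 value was 0.03, on the same side as the Apc value. Over T and NK-like cells the log2 ratio of Cd8b1 differed by −2.04 (0.72 and −1.31), but the log2 odds of a cell having a Cd8b1 UMI at 1500 UMIs were 0.39 (−0.08 to 0.86) in the B6 pair.

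Foxp3 over T and NK-like cells was lower in the B6 MR library and higher in the Apc MR-feces library in CPM, a difference of 2.35. At 1500 UMIs per cell the log2 odds of a cell having a Foxp3 UMI in the Apc pair were 0.67 (−0.90 to 1.98), from 6 of 518 and 28 of 3837 cells, so that counting error and a difference between the libraries cannot be told apart. Fewer UMIs per cell in the MR-feces library lower such a share rather than raise it. Thinning matched UMIs but not detected genes: the thinned cells of the MR-feces and control-feces libraries had medians of 766.5 and 912 genes in the CD8, gamma-delta T or NK-like class and 674 and 896 in CD4 T-like cells. Free RNA did not account for the transcripts, which were found in at most 0.104% of B-like cells against at least 4.24% of CD4 T-like cells. The B6 difference was not in Foxp3 RNA alone: each of the other 7 regulatory T cell markers lay below 0, with a median of −0.57 (−0.71 to −0.43). In the Apc pair a difference in Foxp3 RNA alone stays open. The median there was 0.68, with Tnfrsf4 at 1.95 and Tnfrsf18 at 1.09 but Ikzf2 at −0.69 and Ctla4 at −0.55. These markers are not particular to regulatory T cells in these classes. Ikzf2 had 10429 and 15562 UMIs in the B6 MR and control libraries, far more than Foxp3. Il2ra, Tnfrsf4 and Tnfrsf18 are also in the activation list and Ctla4 in the inhibitory receptor list. In neither pair can a difference in regulatory T cells be told apart from one in activation. With clusters weighted alike the Apc ratio of Foxp3 was −1.32. Whether feces of MR-diet donors act on regulatory T cells stays an untested hypothesis, which replicate libraries of equal depth would test.

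B-like and plasma-like cells together took a larger share of named immune cells in the MR library of both pairs, with log2 odds of 1.03 in the B6 pair and 1.65 in the Apc pair, both with intervals above 0. Without a cell filter the values were 0.95 and 1.61 (1.46 to 1.75). Named immune cells then numbered 4848 and 4666 in the MR and control libraries of the B6 pair, against 4811 and 4585. In the Apc pair they numbered 3863 and 5147, against 3947 and 5183. The barcodes let back in thus added few named cells, so loss of shallow cells in the filter is not excluded. Among all named immune cells, the Apc log2 odds of B-like cells changed sign after thinning to 1500 UMIs and were 0.17 (−0.03 to 0.37) with the stricter cell filter. Relative to T and NK-like cells alone, a denominator chosen afterwards, the log2 odds of being B-like in the Apc pair were 1.40, and 0.85 (0.55 to 1.15) after thinning. Thinning left 15.8% of B-like and 22.8% of T and NK-like cells of the MR-feces library. Since it selects cells by depth, the thinned value covers only the deeper cells of that library and cannot exclude depth. For plasma-like cells, depth cannot be told apart from other causes, because thinning left 93.9% of them there and so raised their own log2 odds, to 5.23, and for lymphoid follicle tissue neither, because at resolution 2.0 the log2 odds of a B-like or germinal centre B-like cell being germinal centre B-like were 0.24 (−0.57 to 1.09) in the Apc pair. An effect of the diet or of the feces on the B cell lineage stays an untested hypothesis, which counting follicles and plasma cells in tissue sections of several mice per group would test.

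Type I interferon response genes in B-like cells lay above all genes in the B6 pair (0.22) and below them in the Apc pair (−0.57), a difference of −0.80. After thinning the Apc value was −0.92 (−1.49 to −0.55), from 153 MR-feces and 612 control-feces cells with medians of 636 and 813 genes. Thinning largely keeps the expected CPM of summed counts, so it cannot exclude an effect of depth. Free RNA at the level estimated in T and NK-like cells did not account for the value, which was −0.58 (−0.86 to −0.39) after subtraction. Clusters that hold mostly 1 library could account for part of the Apc value, which was −0.24 (−0.86 to 0.32) with clusters weighted alike. That setting rests on 34 MR-feces cells of cluster 0 and 21 control-feces cells of cluster 17. A difference within clusters therefore cannot be told apart from one between clusters. An effect of the donors' diet through the feces stays an untested hypothesis, which measuring interferon in replicate recipients would test.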

How the results depend on the processing

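The alternatives were chosen before the data were examined, except T and NK-like cells as 1 class. The sign was kept in 156 of 174 share values, 819 of 866 list values and 563 of 576 gene values. Of the others, 6, 7 and 8 belong to results whose interval at the settings used throughout left out 0, and are called reversed here whatever their own interval, and 12, 40 and 5 to results whose interval there included 0. Median-of-ratios scaling and CPM without ribosomal, mitochondrial and immunoglobulin genes shift all genes alike and cannot move a list relative to all genes, so they are not among the list values. No paired analysis was possible because each group had 1 library and the libraries share no mice. With 1 library per group and a median of 1222.5 UMIs per barcode in the Apc MR-feces library, small differences in rare cells and weak genes could not be seen. Shares below are log2 odds, lists are medians minus all genes and genes are log2 ratios in CPM. The cause was not tested unless stated. Shares from new clusterings also reflect their naming, which left out the condition on top markers of other classes.

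With the stricter cell filter, shares of the B6 pair were 1.12 for B-like cells and 0.31 (−0.04 to 0.67) for plasma-like cells, and in the Apc pair 0.17 for B-like cells, 0.28 for CD4 T-like cells (reversed), −1.05 for CD8, gamma-delta T or NK-like cells and 3.24 for plasma-like cells. The type 17 list in CD4 T-like cells, B6 pair, was 0.0271 (reversed). The activation list, Apc pair, was 0.59 in CD4 T-like and −0.13 (reversed) in CD8, gamma-delta T or NK-like cells. Ccl5 in CD4 T-like cells, B6 pair, was −0.28 and Pnlip in plasma-like cells, B6 pair, 6.34 (both reversed). Without doublet removal, Pnlip in plasma-like cells, B6 pair, was 6.90 and the class II presentation list in macrophage-like cells, B6 pair, −0.0859 (both reversed).

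The share of CD4 T-like cells in the Apc pair was −1.30 without a cell filter, −1.50 at resolution 0.5, 0.22 (reversed) at resolution 2.0 and −1.45 with another seed. At resolution 2.0 that of CD8, gamma-delta T or NK-like cells was −1.47. Among immune cells other than B and plasma cells, CD4 T-like cells were at −0.11 in the B6 and −1.38 in the Apc pair, and CD8, gamma-delta T or NK-like cells at 0.0384 and 0.63 (both reversed), which follows in part from the smaller denominator. B-like, germinal centre B-like and plasma-like cells have no value there by construction. Thinned to 1500 UMIs and clustered again, the Apc shares were −0.14 for B-like cells (reversed), −1.70 for CD8, gamma-delta T or NK-like cells, 4.78 for plasma-like cells and 0.22 for plasmacytoid dendritic-like cells (reversed). ILC3-like and dendritic-like cells had no named cluster, and so no value, with the stricter filter, without a filter, at resolution 0.5 or after thinning, and ILC3-like cells also with another seed.

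With each cell thinned to 1500 UMIs, the activation list in CD4 T-like cells, B6 pair, was −0.46, the cytotoxic effector list in CD8, gamma-delta T or NK-like cells, Apc pair, 0.43, Trac in T and NK-like cells, Apc pair, −0.14 (reversed), and the immediate early and heat shock (dissociation) list in CD4 T-like cells, B6 pair, was 0.0179 (reversed). With clusters weighted alike, the activation list in CD4 T-like cells, Apc pair, was 0.58, the cytotoxic effector list in CD8, gamma-delta T or NK-like cells, Apc pair, was 0.71, and the tissue residency and gut homing list in CD8, gamma-delta T or NK-like cells, Apc pair, was 0.0149 (reversed). The transsulfuration, glutathione and sulfide oxidation list in CD8, gamma-delta T or NK-like cells, Apc pair, was −0.15 (reversed). In T and NK-like cells, Apc pair, Cd4 was 0.27, Trac −0.0459, Foxp3 −1.32 and Ifng 0.10 (all reversed). With members of at least 1 UMI, the type I interferon response list in CD8, gamma-delta T or NK-like cells, Apc pair, was −0.43. With free RNA subtracted, the cytotoxic effector list in B-like cells, B6 pair, was 0.0274 (reversed). With T and NK-like cells as 1 class, the activation list in the Apc pair was 0.17. These 2 scalings changed the sign of no gene, and a prior count of 2 that of no list or gene. Among smaller classes of the Apc pair whose intervals at the settings used throughout included 0, the log2 odds of the share of germinal centre B-like cells, Apc pair, went from −0.05 to 1.63 with the stricter filter, 1.18 at resolution 2.0 and 2.16 after thinning. The log2 odds of the share of macrophage-like cells, Apc pair, went from −0.28 to 0.61 with the stricter filter, −1.14 without a filter and 2.02 after thinning, and those of the share of neutrophil-like cells, Apc pair, from 0.53 to −1.57 with the stricter filter. Thinning left out cells of few UMIs, so the values after it also reflect which classes hold deep cells.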

Other observations

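Intestinal plasma cells mostly secrete immunoglobulin A, which coats gut bacteria. Of plasma-like cells, 94.3%, 98.6%, 94.6% and 92.5% were counted as having IgA as main heavy chain in the B6 control, B6 MR, Apc control-feces and Apc MR-feces libraries. IgG was the main chain in 2.86%, 1.40%, 3.23% and 4.14%, and IgM in 2.86%, 0 of 214 cells, 2.15% and 3.41%. Ties and cells without a heavy chain UMI counted as IgA. An Igha UMI was found in 100%, 100%, 92.5% and 98.8% of plasma-like cells. Lambda was the main light chain in 8 of 140, 29 of 214, 11 of 93 and 40 of 411 of them, with ties counted as kappa. Intestinal gamma-delta T cells carry characteristic receptor segments. Segment UMIs were summed over the whole CD8, gamma-delta T or NK-like class, not over gamma-delta T cells alone. In the same order of libraries, 61.5%, 64.6%, 63.1% and 42.9% of cells of the class had a Trac UMI. Trgv2 made up 71.6%, 75.9%, 72.7% and 80.0% of gamma V segment UMIs, of which there were 2982, 2959, 4728 and 771. Tcrg-V7, typical of intestinal intraepithelial cells, made up 8.95%, 7.67%, 8.16% and 4.93%. Trdv5 made up 32.7%, 29.8%, 37.1% and 26.1% of delta V segment UMIs, of which there were 471, 467, 421 and 92.

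Smaller classes, as shares of named immune cells in MR against control, were as follows. Germinal centre B-like cells, in which antibody genes mutate, stood at 2.29% against 1.57% in the B6 pair (odds ratio 1.47, 1.08 to 2.01) and 1.19% against 1.23% in the Apc pair (0.964, 0.646 to 1.43). The 10 top genes of this cluster, such as Mki67 and Top2a, mark dividing cells of any type. In the order of libraries above, 18 of 72, 22 of 110, 45 of 64 and 10 of 47 of its cells had a Cd3e UMI and 54, 96, 21 and 35 a Cd79a UMI. Cd3e was found in 2.52% to 3.23% of cells of the B-like cluster 0, which are shallower, and in 17.9%, 13.1%, 24.7% and 3.65% of the plasma-like cluster 12. The class thus held T cells in the Apc libraries, while in the B6 libraries these shares do not exclude background. At resolution 2.0 the shares of germinal centre B-like cells with a UMI were 6.90%, 12.2%, 18.2% and 2.63% for Cd3e and 89.7%, 96.9%, 90.9% and 89.5% for Cd79a. The odds ratio of the class was then 1.62 (1.16 to 2.29) in the B6 pair and 2.27 (1.30 to 4.03) in the Apc pair. With the stricter cell filter the Apc value was 3.09 (1.77 to 5.56). ILC3-like cells, named for innate lymphoid cells that make interleukin-22, stood at 0.686% against 0.502% (1.37, 0.779 to 2.45) and 0.988% against 0.212% (4.69, 2.35 to 10.2), but in the 4 libraries 9 of 23, 12 of 33, 6 of 11 and 12 of 39 of these cells had a Cd3e UMI, and 8, 11, 5 and 9 of them a Trdc UMI too, so that the class also held gamma-delta T cells. Dendritic-like cells stood at 1.62% against 1.61% (1.00, 0.720 to 1.40) and 1.04% against 0.482% (2.17, 1.28 to 3.72), and neutrophil-like cells at 0.478% against 0.807% (0.591, 0.334 to 1.02) and 0.557% against 0.386% (1.45, 0.752 to 2.80). Plasmacytoid dendritic-like cells, which make type I interferon, stood at 0.582% against 0.545% (1.07, 0.599 to 1.91) and 0.532% against 1.23% (0.428, 0.248 to 0.711).

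The unnamed cluster 7, whose cells had few UMIs and whose 10 top genes included G0s2, Retnlg and Cxcl2 as in the neutrophil-like cluster 20, held 2.74% and 1.56% of kept cells in the B6 control and MR libraries, 0.0189% in the Apc control-feces library and 0 of 3962 cells in the Apc MR-feces library, where the upper end of the interval was 0.0931%.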
